A study of Homo sapiens with 18 samples.

How the data were processed

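The series comprised 18 RNA-seq libraries of LNCaP cells, a human prostate cancer line. Per the labels' protocols, cells kept in medium with 10% fetal bovine serum were transfected with siRNA by a lipid reagent (RNAiMAX) for 48 h or 96 h, RNA was extracted with Trizol, and stranded polyA libraries were made with the Nugen Universal Plus mRNA-seq kit and 15 amplification cycles. The siRNAs were a control (siNC), siPDIA1 against PDIA1, whose gene symbol is P4HB, and siPDIA5 against PDIA5. Each of the 6 combinations of siRNA and time had 3 libraries, numbered 1 to 3 in the labels. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The siRNA sequences, and whether each siRNA was a pool, are not given in the sources used here.

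The values were those of the deposited table, in which the authors gave RPKM (reads per kilobase of gene, scaled to a common number of reads) for each gene and library, with no counts. The submitters' processing notes name cutadapt 1.8, STAR 2.7.0f, featureCounts, DESeq2 and R 3.4.1 and the builds GRCh38 and hg38, without roles or order. The annotation release, the strand setting of the counting, the treatment of reads that fit several genes and the reads that RPKM was scaled to are not given in the sources used here. Reads of antisense or overlapping genes, paralogs and pseudogenes, and short features can therefore be assigned to the wrong gene, and such features are reported as uncertain. No test on counts was run.

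The table held 59385 genes, of which 57118 had an identifier in GENCODE 29 without regard to its version (36057 with the same version). Coordinates are those of GENCODE 29 on GRCh38. In each library the value times the exon length in GENCODE 29 fell on whole multiples of 1 step for 99.6% to 99.8% of values of at most 20 reads, within 0.1 read. The step gave an estimated 29.2 to 43.9 M reads assigned to genes per library (median 37.3 M). These depths rest on that fit and were not used in any test. A total of 20154 genes were listed at 0 in all 18 libraries.

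Values were analysed as log2(RPKM + 1), with the pseudocount of 1 chosen before the data were examined, as were the comparisons, gene lists, rule for named genes and most alternatives. A fold change on this scale understates the change of genes with low RPKM. The 11685 genes with a mean RPKM of at least 1 over the 18 libraries were tested, of which 9996 were protein-coding and 141 had an exon length under 200 bases. A linear model with a mean for each of the 6 groups was fitted to all 18 libraries with limma 3.58.1 (R 4.3.3, empirical Bayes with a mean-variance trend). P-values were adjusted by Benjamini and Hochberg over all tested genes in each comparison, and genes with an adjusted p under 0.05 were called. Errors of log2 fold changes are standard errors from this model, and errors of RPKM values are SD over 3 libraries. The comparisons were each siRNA against siNC at 48 h and 96 h, siPDIA1 against siPDIA5 at each time, the difference of each siRNA's effect between the times, and siNC at 96 h against 48 h. At each time both knockdowns shared the same control libraries, so agreement between them was set beside 100 simulations of unchanged groups and beside the overlap of independent lists.

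The genes named were P4HB, PDIA5, KLK3, KLK2, TMPRSS2 and FKBP5 among those fixed by name, then, for each comparison of an siRNA with siNC, the 8 called genes with the largest rise and the 8 with the largest fall among those whose 3 and 3 libraries did not overlap (5 for the other comparisons), and for each list up to 4 members with the smallest adjusted p. Of these the text gives the protein-coding genes and the counts of the others. The 27 lists, written from general knowledge, included the PDI family, ATF4 targets and ER chaperones of the unfolded protein response, NRF2 targets, heat shock, proteasome, S phase, G2/M phase, p53 targets, apoptosis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, mitochondrial ribosome, cytosolic ribosome, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, interferon, NF-kB targets, neuroendocrine genes, extracellular matrix, and markers of stromal, basal epithelial, leukocyte and endothelial cells. Some genes and lists fixed beforehand are not reported here. None of the 13 leukocyte markers reached the filter, so 26 lists were tested, and list p-values were adjusted over these 26. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. A list was called at an adjusted p under 0.05 with the preset correlation.

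The alternatives fixed beforehand were a pseudocount of 0.25, no filter, a mean RPKM of at least 5, median centring, quantile normalization, a block for the replicate number, a fit of only the groups compared, no trend, the estimated correlation, and leaving out each replicate in turn. Added after the data were seen were protein-coding genes alone, a fit without the 2 libraries farthest from their group mean, the list tests under settings other than the estimated correlation, and all settings for the genes fixed by name in comparisons other than those with siNC. The 3′ UTR word scan was also added then. It used the longest annotated 3′ UTR of 9929 protein-coding genes (at least 50 bases), removed the trend of the log2 fold change with 3′ UTR length and base composition, and ranked genes with and without each 7-base word present in at least 50 genes. The largest absolute z in 100 permutations of the genes, 4.99, was the threshold. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.

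The fit was tested on simulated data with the real means and spreads of the 11685 genes, in which 50 genes each were changed by 1.25-fold, 1.5-fold, 2-fold and 3-fold. For siPDIA1 at 48 h it recovered 18%, 46%, 76% and 92% of them with 3 false calls, and at 96 h 30%, 56%, 72% and 98% with 8. For siPDIA5 at 48 h it recovered 30%, 52%, 80% and 94% with 9 false calls, and at 96 h 26%, 44%, 78% and 96% with 6. In the siPDIA1 48 h simulation camera called a list of 50 genes raised by 0.2 on the log2 scale and did not call an unchanged list. The simulated noise was independent between genes. It therefore does not test false calls of lists with correlated members, such as cytosolic ribosome (estimated correlation 0.68). The word scan ranked a word planted with a log2 change of -0.05 in the siPDIA1 48 h simulation at rank 1 (z -6.87), and passed 0 words when nothing was planted.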

Results

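Gene expression was measured by RNA-seq in LNCaP cells, a human prostate cancer line, after knockdown of PDIA1 (gene symbol P4HB) or PDIA5. Both are protein disulphide isomerases, enzymes of the endoplasmic reticulum (ER) that form and rearrange disulphide bonds in folding proteins. Cells received a control siRNA (siNC), siPDIA1 or siPDIA5 and were collected at 48 h or 96 h, with 3 libraries in each of the 6 groups. The deposited RPKM values corresponded to an estimated 29.2 to 43.9 M reads on genes per library (M, 1e6), and 20813 to 29505 genes had a value above 0. Replicate libraries of a group correlated at 0.986 to 0.994 (Pearson, log2 values across genes, which are not independent replicates), and every pair differed by more than counting noise. Mitochondrially encoded transcripts took 9.50% to 9.88% of the estimated reads in the siNC libraries at 48 h, 10.1% to 10.5% after siPDIA1 and 10.6% to 11.2% after siPDIA5. At 96 h these shares were 10.1% to 11.1%, 10.7% to 11.5% and 12.6% to 13.9%. The library of siPDIA1 replicate 1 at 96 h stood farthest from its group mean, with a root mean square deviation of 0.247 (log2) against 0.109 to 0.179 in the other 17. The first principal component held 32.8% of the variance and the second 21.6%. Markers of other cell types were low, with KRT5 of basal cells at most 0.0130 RPKM, DCN of fibroblasts at most 0.0103 and PTPRC of leukocytes at most 0.0263 in any library, and 0 of the 13 leukocyte markers entered the tests.

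**Figure D1:**
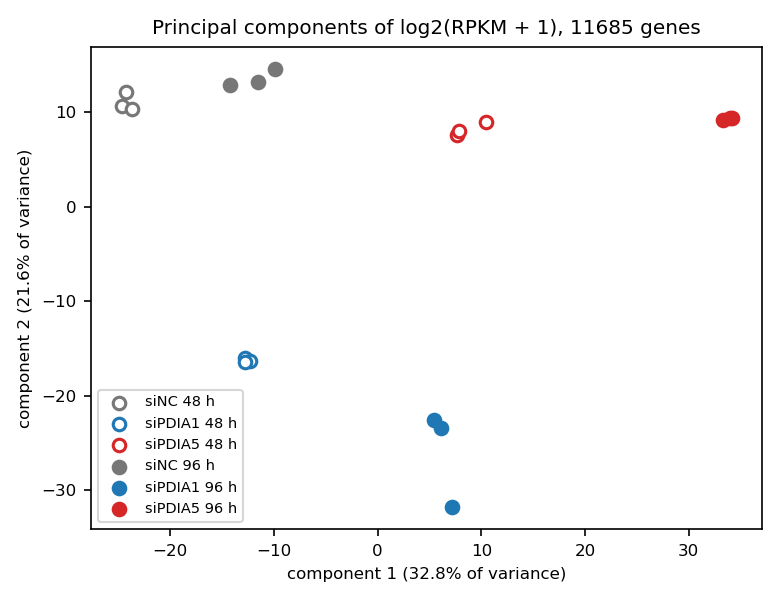
Principal components of log2(RPKM + 1) over the 11685 tested genes, with component 1 (32.8% of the variance) on the horizontal and component 2 (21.6%) on the vertical axis. Each point is 1 library, open at 48 h and filled at 96 h, in grey for siNC, blue for siPDIA1 and red for siPDIA5, and siPDIA1 replicate 1 at 96 h lies at -31.8 on component 2 against -22.6 and -23.4 for the other libraries of its group.

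Each siRNA lowered its own target in every library that received it. P4HB (ENSG00000185624.16, chromosome 17, 81843159 to 81860694, minus strand) was at 66.9 ± 0.761 RPKM (SD, n = 3) in siNC and 5.73 ± 0.458 after siPDIA1 at 48 h, which left 8.58% of the control level, and at 68.9 ± 4.75 and 9.16 ± 0.953 at 96 h, which left 13.3%. The siPDIA1 libraries lay at 5.29 to 6.20 RPKM against 66.3 to 67.7 in siNC at 48 h, and at 8.17 to 10.1 against 63.5 to 72.4 at 96 h. PDIA5 (ENSG00000065485.20, chromosome 3, 123067062 to 123225227, plus strand) was at 14.0 ± 0.464 RPKM in siNC and 1.55 ± 0.195 after siPDIA5 at 48 h (11.1% left), with libraries at 1.33 to 1.67 against 13.5 to 14.4. At 96 h it was at 14.9 ± 1.22 and 1.40 ± 0.20 RPKM (9.40% left), with libraries at up to 1.63 against 13.5 to 15.7. On the log2(RPKM + 1) scale used for every fold change here, which understates changes of low genes, the change of P4HB with siPDIA1 was -3.34 ± 0.07 at 48 h and -2.78 ± 0.07 at 96 h (log2 fold change ± SE, limma adjusted p = 2.23e-14 and 4.48e-14). That of PDIA5 with siPDIA5 was -2.55 ± 0.08 and -2.73 ± 0.08 (adjusted p = 2.99e-12 and 4.74e-13). P4HB rose in the PDIA5 knockdown, to 129 ± 3.13 RPKM at 48 h (log2 fold change 0.94 ± 0.07, adjusted p = 2.35e-08) and 124 ± 5.62 at 96 h (0.84 ± 0.07, adjusted p = 4.29e-08). PDIA5 was at 16.4 ± 0.828 and 15.9 ± 1.46 RPKM in the PDIA1 knockdown, and neither difference from siNC passed the test (adjusted p = 0.0533 and 0.411). The 48 h difference was called at a mean RPKM of at least 5 (0.0442), with quantile normalization (0.0389), in a fit of only the groups compared (0.0144) and with protein-coding genes alone (0.0450).

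**Figure D2:**
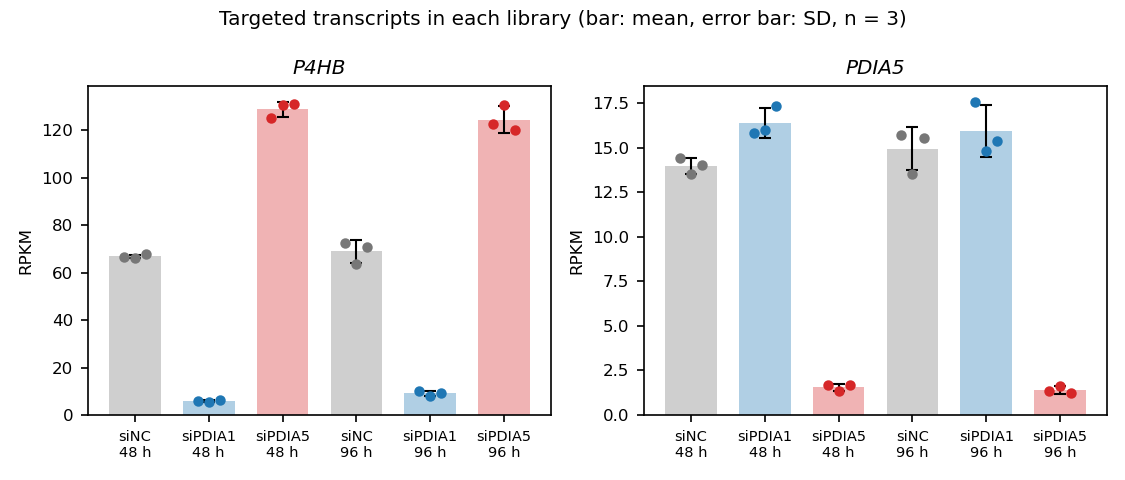
RPKM of P4HB (left) and PDIA5 (right) in each of the 18 libraries, by siRNA and time, with bars for the group mean and error bars for the SD (n = 3). P4HB is at most 10.1 RPKM in any siPDIA1 library and PDIA5 at most 1.67 in any siPDIA5 library, and the P4HB means after siPDIA5 are 129 at 48 h and 124 at 96 h.

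The siPDIA1 libraries were compared with siNC at 48 h to find the early transcript changes after loss of PDIA1. Genes that rose included CAMK2N1, an inhibitor of the kinase CaMKII (log2 fold change 2.01 ± 0.06, SE, n = 3 per group), SLC7A8, a neutral amino acid transporter (1.97 ± 0.07), TPM4, a tropomyosin of the actin cytoskeleton (1.97 ± 0.06), TM4SF1, a membrane protein of the tetraspanin-like family (2.09 ± 0.12), OGFR, the opioid growth factor receptor (1.81 ± 0.08), and GANAB, the catalytic subunit of ER glucosidase II, which trims N-glycans on folding proteins (1.76 ± 0.05). Besides P4HB, the genes that fell most included ELOVL7, a fatty acid elongase (-2.55 ± 0.08), SLC45A3, a prostate-enriched transporter (-2.20 ± 0.06), HAUS1, a subunit of the augmin complex of the mitotic spindle (-2.04 ± 0.14), and B4GALT5, a galactosyltransferase of glycolipid synthesis (-1.99 ± 0.12). In RPKM, CAMK2N1 (chromosome 1, 20482391 to 20486220, minus strand) went from 21.0 to 87.3 and SLC45A3 (chromosome 1, 205657851 to 205680459, minus strand) from 140 to 29.6. The largest adjusted p among these genes was 2.95e-08 (HAUS1), and in each the 3 knockdown libraries did not overlap the 3 controls. In all, 3897 of 11685 genes were called, 1866 higher and 2031 lower, of which 69 rose and 76 fell by at least 2-fold. The other 5 features among the 8 largest changes in each direction were short, antisense, pseudogene or unannotated, so their reads are uncertain. List medians here and elsewhere are of log2 fold changes.

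Among the genes fixed beforehand, FKBP5, a co-chaperone, rose after siPDIA1 at 48 h (0.82 ± 0.07, adjusted p = 2.73e-07), and KLK3, which encodes PSA, was slightly lower (-0.15 ± 0.05, adjusted p = 0.0274). KLK2, a kallikrein protease close to KLK3 in sequence (-0.13 ± 0.07, adjusted p = 0.138), and TMPRSS2, a membrane serine protease (-0.07 ± 0.04, adjusted p = 0.235), did not pass. The KLK3 call was lost without the expression filter (adjusted p = 0.0843), with quantile normalization (0.0524) and without siNC replicate 3 (0.104) or siPDIA1 replicate 1, 2 or 3 (0.0833, 0.0621 and 0.0544) at 48 h, and KLK2 was called in a fit of only the groups compared (0.0237).

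Cell cycle genes were lower at this time. Of 55 G2/M genes 1 rose, 31 fell and 23 did not pass (2 and 38 adjusted over the list alone). Among them were CDCA8 of the chromosomal passenger complex (-0.81 ± 0.07) and the mitotic kinase PLK1 (-0.50 ± 0.06), and the list was called (median -0.27, camera adjusted p = 2.12e-06, adjusted p = 0.255 with an estimated correlation). Of 44 S phase genes 2 rose, 15 fell and 27 did not pass (3 and 15 adjusted over the list alone). Among them were GMNN, the licensing inhibitor geminin (-1.39 ± 0.11), and the replicative helicase subunit MCM2 (-0.42 ± 0.04). For the S phase list, the median was -0.10 (camera adjusted p = 0.0257, adjusted p = 0.426 with an estimated correlation). The mitochondrial ribosome list was also lower, and of 56 genes 1 rose, 15 fell and 40 did not pass (1 and 15 adjusted over the list alone). Foremost was MRPL20 (-1.41 ± 0.08). For the mitochondrial ribosome list, the median was -0.12 (camera adjusted p = 0.0257, adjusted p = 0.628 with an estimated correlation), beside a share of mitochondrially encoded reads of 10.1% to 10.5% against 9.50% to 9.88% in siNC. Of 20 heat shock genes 2 rose, 10 fell and 8 did not pass (2 and 11 adjusted over the list alone). Among them the cytosolic chaperone HSP90AB1 (-0.68 ± 0.04) and its co-chaperone STIP1 (-0.57 ± 0.04) were lower (median -0.12, camera adjusted p = 0.0342, adjusted p = 0.384 with an estimated correlation). None of these 4 list calls held with an estimated correlation. The heat shock call was also lost with quantile normalization (adjusted p = 0.182), the replicate block (0.0545), a fit of only the groups compared (0.0653), protein-coding genes alone (0.0775) and without siNC replicate 1 (0.0581) or 3 (0.0555) at 48 h. The mitochondrial ribosome call was lost with quantile normalization (0.0578), protein-coding genes alone (0.0505) and without siNC replicate 1 at 48 h (0.0581), and the S phase call with protein-coding genes alone (0.0505). Other lists were not called. Of the 17 measured PDI family genes 6 rose, 3 fell and 8 did not pass (9 and 3 adjusted over the list alone), and the list's median (0.11) and its mean (-0.07), which includes P4HB itself, differed in sign (camera adjusted p = 0.345). The thioredoxin-related TMX3 rose (0.54 ± 0.08) and TXNDC15 fell (-0.27 ± 0.06). Of 41 ER chaperone genes 7 rose, 5 fell and 29 did not pass. Among them the oxidase ERO1A was higher (0.64 ± 0.09) and the lectin chaperone CANX lower (-0.55 ± 0.06). Of 34 ATF4 targets 11 rose, 7 fell and 16 did not pass. Of 25 apoptosis genes 10 rose, 4 fell and 11 did not pass. Among them the survival factor BCL2L1 (0.68 ± 0.06) and the caspase CASP6 (0.60 ± 0.10) were higher (camera adjusted p = 0.158). Of 18 fatty acid synthesis genes 6 rose, 3 fell and 9 did not pass, with a median of -0.02 and a mean of 0.01. Median, mean and camera direction also differed in sign for cytosolic ribosome (0.00, -0.01, up) and basal (-0.01, 0.05, up).

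At 96 h after siPDIA1, CAMK2N1 rose from 13.2 ± 1.08 to 189 ± 2.16 RPKM (log2 fold change 3.75 ± 0.06, n = 3 per group). The matrix metalloprotease MMP7 (3.48 ± 0.15), the secreted phospholipase PLA2G2A (3.12 ± 0.13), the vesicle protein SYT4 (3.02 ± 0.05), the ephrin ligand EFNB2 (2.62 ± 0.14), the antiproliferative factor BTG1 (2.43 ± 0.06) and DIO3, which inactivates thyroid hormone (2.42 ± 0.14), also rose. ELOVL7 (-3.20 ± 0.08), SLC45A3 (-3.02 ± 0.06), the transcriptional regulator HES6 (-2.57 ± 0.10), the growth factor VEGFB (-2.29 ± 0.13), PRUNE2 (-2.24 ± 0.15) and the desmosomal cadherin DSC2 (-2.24 ± 0.11) fell. SLC45A3 was at 153 ± 8.58 RPKM in siNC and 18 ± 1.37 after siPDIA1. The largest adjusted p among these genes was 1.11e-08 (PRUNE2), and their 3 and 3 libraries did not overlap. A total of 5294 genes were called, 2344 higher and 2950 lower, with 164 up and 143 down by at least 2-fold. Median centring gave 2624 higher and 2640 lower and quantile normalization 2656 and 2726. MMP7 and DIO3 were below 1 RPKM in siNC (0.884 and 0.749), so their fold changes are understated.

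TMPRSS2 fell at 96 h (-0.30 ± 0.04, adjusted p = 2.97e-05), whereas KLK3 (0.27 ± 0.05, adjusted p = 0.000291) and FKBP5 (0.50 ± 0.07, adjusted p = 2.82e-05) rose and KLK2 did not pass (-0.08 ± 0.07, adjusted p = 0.342).

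Of 44 S phase genes 1 rose, 32 fell and 11 did not pass after siPDIA1 at 96 h (1 and 33 adjusted over the list alone). They included the ribonucleotide reductase subunit RRM2 (-0.69 ± 0.05), MCM2 (-0.57 ± 0.04) and the flap nuclease FEN1 (-0.65 ± 0.05), and this call held with both correlation settings (median -0.44, camera adjusted p = 3.86e-08, adjusted p = 0.0465 with an estimated correlation). Of 55 G2/M genes 1 rose, 35 fell and 19 did not pass (2 and 36 adjusted over the list alone). Among them CDCA8 (-0.90 ± 0.07) and PLK1 (-0.61 ± 0.06) were lower (median -0.31, camera adjusted p = 1.82e-06, adjusted p = 0.0943 with an estimated correlation). Of 41 ER chaperone genes 15 rose, 3 fell and 23 did not pass (15 and 3 adjusted over the list alone). Among them ERO1A (1.06 ± 0.09), the isomerase PDIA4 (0.39 ± 0.04) and the lectin CALR (0.38 ± 0.04) were higher and CANX lower (-0.57 ± 0.06). The median over ER chaperone genes was 0.14 (camera adjusted p = 0.0203, adjusted p = 0.0943 with an estimated correlation). Of 34 ATF4 targets 3 rose, 16 fell and 15 did not pass (4 and 19 adjusted over the list alone). Among them the tRNA exporter XPOT (-1.15 ± 0.08), the serine-synthesis enzyme PSAT1 (-0.62 ± 0.05) and the glycine transporter SLC6A9 (-1.03 ± 0.09) were lower (median -0.19, camera adjusted p = 0.0117, adjusted p = 0.106 with an estimated correlation). Of 24 cholesterol synthesis genes 2 rose, 12 fell and 10 did not pass (2 and 12 adjusted over the list alone). Among them HMGCS1 (-0.91 ± 0.08) and the sterol reductase TM7SF2 (-0.68 ± 0.05) were lower (median -0.16, camera adjusted p = 0.0431, adjusted p = 0.104 with an estimated correlation). Cytosolic ribosome genes were higher, and of 74 genes 32 rose, 1 fell and 41 did not pass (32 and 1 adjusted over the list alone). Foremost were RPS20 (0.49 ± 0.08) and RPL11 (0.40 ± 0.06) while RPL22 fell (-1.39 ± 0.07). The median over cytosolic ribosome genes was 0.20 (camera adjusted p = 0.000112, adjusted p = 0.596 with an estimated correlation). Mitochondrial ribosome genes were lower, and of 56 genes 6 rose, 22 fell and 28 did not pass (6 and 22 adjusted over the list alone). The median over mitochondrial ribosome genes was -0.16 (camera adjusted p = 0.0355, adjusted p = 0.582 with an estimated correlation). Mitochondrially encoded transcripts, at 10.7% to 11.5% of the reads against 10.1% to 11.1% in siNC, were not called (1 rose, 1 fell and 11 did not pass, median -0.02, mean 0.06, camera adjusted p = 0.789). The cytosolic ribosome call was lost without siNC replicate 2 at 96 h (median 0.11, adjusted p = 0.0613), and the mitochondrial ribosome and cholesterol calls without siNC replicate 1 at 96 h (adjusted p = 0.130 and 0.0804) or siPDIA1 replicate 3 at 96 h (0.0845 and 0.0618) and, for the former, siNC replicate 3 at 96 h (0.0747). Both were also lost with quantile normalization (0.105 and 0.118), at a mean RPKM of at least 5 (0.0837 and 0.0819), in a fit of only the groups compared (0.0696 and 0.0968) and with protein-coding genes alone (0.0663 and 0.0699), and the cholesterol call with the replicate block (0.0531).

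Other lists were not called at 96 h after siPDIA1. Of 30 p53 targets 7 rose, 9 fell and 14 did not pass. Among them the cell cycle inhibitor CDKN1A was lower (-1.20 ± 0.04) and the kinase PLK2 higher (1.14 ± 0.08). The list had a median of -0.00, a mean of -0.07 and a camera direction up (adjusted p = 0.999). Of 26 NRF2 targets 10 rose, 5 fell and 11 did not pass. Among them malic enzyme ME1 was higher (0.96 ± 0.06) and ferritin light chain FTL lower (-0.66 ± 0.07), and the list was not called (camera adjusted p = 0.117). Of 18 fatty acid synthesis genes 4 rose, 10 fell and 4 did not pass. Among them the acyl-CoA synthetase ACSL3 (-0.79 ± 0.06) and ELOVL6 (-0.82 ± 0.08) were lower (camera adjusted p = 0.164). Of 9 NF-kB targets 1 rose, 3 fell and 5 did not pass. Among them NFKB1 was higher (0.85 ± 0.07) and NFKB2 lower (-0.56 ± 0.05), and the list had a median of 0.01 and a mean of -0.02 (camera adjusted p = 0.999). Of 27 hypoxia and glycolysis genes 5 rose, 4 fell and 18 did not pass, with a median of -0.01 and a mean of 0.04 (camera adjusted p = 0.789). Fibronectin, FN1, rose (1.53 ± 0.09), while the extracellular matrix list of 15 was not called (5 rose, 4 fell and 6 did not pass, camera adjusted p = 0.652).

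The siPDIA5 libraries were compared with siNC at 48 h in the same way. The largest rises were in PLA2G2A (log2 fold change 3.34 ± 0.13, n = 3 per group), THRSP, a regulator of lipogenesis (2.62 ± 0.23), the secreted glycoprotein LRG1 (2.12 ± 0.13), the lectin receptor CLEC7A (2.08 ± 0.13), OGFR (2.02 ± 0.08), ID2, an inhibitor of basic helix-loop-helix factors (1.90 ± 0.11), the protease precursor PGC (1.87 ± 0.10) and SLC7A8 (1.81 ± 0.07). PLA2G2A (chromosome 1, 19975431 to 19980416, minus strand) went from 4.58 ± 1.32 to 54.5 ± 6.44 RPKM. Besides PDIA5, the genes that fell most included PRRC2A, an RNA-binding protein (-2.08 ± 0.07), the kynurenine aminotransferase AADAT (-1.78 ± 0.07), PTGES3, the p23 co-chaperone of HSP90 (-1.74 ± 0.04), and HES6 (-1.72 ± 0.10). The largest adjusted p among these genes was 2.66e-07 (THRSP), and their 3 and 3 libraries did not overlap. In all, 5352 genes were called, 1944 higher and 3408 lower, with 101 up and 109 down by at least 2-fold. The split of directions depended on scaling, since the median of all tested genes lay at -0.0915, and median centring gave 2574 higher and 2420 lower and quantile normalization 2427 and 2489.

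After siPDIA5 at 48 h KLK3 (0.34 ± 0.05, adjusted p = 3.24e-05) and FKBP5 (0.42 ± 0.07, adjusted p = 0.000158) rose, TMPRSS2 (-0.43 ± 0.04, adjusted p = 8.85e-07) fell, and KLK2 did not pass (0.16 ± 0.07, adjusted p = 0.0648) but was called with median centring (0.24, adjusted p = 0.00995), quantile normalization (0.0398), the replicate block (0.0351) and without siPDIA5 replicate 2 at 48 h (0.0380).

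With siPDIA5 at 48 h the S phase and G2/M lists fell and had the lowest medians of the 26 lists tested. Of 44 S phase genes 0 rose, 39 fell and 5 did not pass (0 and 39 adjusted over the list alone). They included thymidylate synthase TYMS (-1.53 ± 0.07), the sliding clamp PCNA (-0.77 ± 0.05) and MCM2 (-0.66 ± 0.04). S phase genes had a median of -0.59 (camera adjusted p = 5.19e-12, adjusted p = 0.00682 with an estimated correlation). Of 55 G2/M genes 1 rose, 49 fell and 5 did not pass (1 and 49 adjusted over the list alone). They included the chromatin protein HMGB2 (-1.14 ± 0.07), CDCA3 (-0.90 ± 0.07) and PLK1 (-0.73 ± 0.06). G2/M genes had a median of -0.66 (camera adjusted p = 1.75e-13, adjusted p = 0.00682 with an estimated correlation). Of 41 ER chaperone genes 19 rose, 7 fell and 15 did not pass (19 and 7 adjusted over the list alone). Among them HERPUD1 of ER-associated degradation (0.64 ± 0.05), PDIA4 (0.46 ± 0.04) and the chaperone HSPA5, also called BiP (0.48 ± 0.04), were higher and the translocon subunit SEC61B lower (-0.86 ± 0.07). ER chaperone genes had a median of 0.22 (camera adjusted p = 0.000309, adjusted p = 0.00682 with an estimated correlation). Of 17 PDI family genes 6 rose, 1 fell and 10 did not pass (6 and 1 adjusted over the list alone). Among them P4HB, PDIA4 and PDIA3 (0.39 ± 0.05) were higher and PDIA5 lower (median 0.10, camera adjusted p = 0.00746, adjusted p = 0.0261 with an estimated correlation), and the call was lost at a mean RPKM of at least 5 (12 genes, adjusted p = 0.0659). NF-kB targets rose, and of 9 genes 6 rose, 1 fell and 2 did not pass (6 and 1 adjusted over the list alone). Foremost were the inhibitor NFKBIA (1.19 ± 0.08), NFKB2 (0.75 ± 0.05) and RELB (0.94 ± 0.11). NF-kB target genes had a median of 0.40 (camera adjusted p = 0.000370, adjusted p = 0.00823 with an estimated correlation). Of 25 apoptosis genes 8 rose, 4 fell and 13 did not pass (8 and 4 adjusted over the list alone). Among them BCL2L1 (0.87 ± 0.06) was higher and BMF, a promoter of cell death, lower (-0.73 ± 0.07). Apoptosis genes had a median of 0.09 (camera adjusted p = 0.0182, adjusted p = 0.0406 with an estimated correlation). The list holds both promoters and inhibitors of cell death, so its direction does not give that of apoptosis. Of 24 cholesterol synthesis genes 10 rose, 2 fell and 12 did not pass (10 and 2 adjusted over the list alone). Among them lanosterol synthase LSS was higher (0.57 ± 0.04) and the thiolase ACAT2 lower (-0.39 ± 0.06), with a list median of 0.16 and camera adjusted p = 0.00746 (adjusted p = 0.0255 with an estimated correlation).

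Other lists called at 48 h after siPDIA5 were lost with an estimated correlation. Of 26 NRF2 targets 14 rose, 2 fell and 10 did not pass (14 and 3 adjusted over the list alone). Among them ME1 (1.07 ± 0.06) and the epoxide hydrolase EPHX1 (0.73 ± 0.05) were higher and GCLM, a subunit of the first enzyme of glutathione synthesis, lower (-0.99 ± 0.07). NRF2 target genes had a median of 0.16 (camera adjusted p = 0.00149, adjusted p = 0.0823 with an estimated correlation). Of 20 heat shock genes 12 rose, 4 fell and 4 did not pass (13 and 4 adjusted over the list alone). Among them the small heat shock proteins HSPB1 (1.37 ± 0.08) and CRYAB (1.0 ± 0.09) were higher and HSP90AB1 lower (-0.22 ± 0.04). Heat shock genes had a median of 0.14 (camera adjusted p = 0.0120, adjusted p = 0.0941 with an estimated correlation). Of 18 fatty acid synthesis genes 8 rose, 4 fell and 6 did not pass (8 and 4 adjusted over the list alone). Among them ME1 and THRSP were higher and ELOVL7 lower (-1.11 ± 0.08). Fatty acid synthesis genes had a median of 0.14 (camera adjusted p = 0.0182, adjusted p = 0.326 with an estimated correlation). Of 15 extracellular matrix genes 5 rose, 3 fell and 7 did not pass (6 and 3 adjusted over the list alone). Among them FN1 (1.11 ± 0.09) and COL18A1 (0.60 ± 0.08) were higher (median 0.13, camera adjusted p = 0.0494, adjusted p = 0.0874 with an estimated correlation). Of 13 mitochondrially encoded genes 6 rose, 0 fell and 7 did not pass (6 and 0 adjusted over the list alone). Among them MT-ND6 was higher (0.30 ± 0.07), as their share of reads was 10.6% to 11.2% against 9.50% to 9.88% in siNC (median 0.17, camera adjusted p = 0.0120, adjusted p = 0.427 with an estimated correlation). Quantile normalization gave this list a median of 0 (adjusted p = 0.985), and it ended the heat shock (0.0757), fatty acid (0.166) and matrix (0.0986) calls. These 4 calls were also lost at a mean RPKM of at least 5 (mitochondrially encoded 0.0504, heat shock 0.0985, fatty acid 0.123, matrix 0.0879). The matrix call was lost as well with a pseudocount of 0.25 (0.0523), a fit of only the groups compared (0.0546), protein-coding genes alone (0.0626), without siNC replicate 1 (0.0527), siNC replicate 2 (0.0560) or siPDIA5 replicate 3 (0.0688) at 48 h, and without the 2 libraries farthest from their group mean (0.0571). ATF4 targets were not called (8 rose, 9 fell and 17 did not pass of 34, median -0.04, camera direction up, adjusted p = 0.488), nor were proteasome genes (2 rose, 4 fell and 25 did not pass of 31, median 0.01, mean -0.02, camera adjusted p = 0.488).

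At 96 h after siPDIA5, PLA2G2A rose from 8.40 ± 0.891 to 393 ± 19.3 RPKM (log2 fold change 5.39 ± 0.13, n = 3 per group). DIO3 (4.62 ± 0.14), the nitric oxide synthase NOS3 (4.51 ± 0.11), the small heat shock proteins HSPB8 (3.01 ± 0.10) and CRYAB (2.97 ± 0.09), CAMK2N1 (2.98 ± 0.06), HSD11B2, which inactivates cortisol (2.93 ± 0.07), and the haem-degrading enzyme HMOX1 (2.80 ± 0.11) rose. Besides PDIA5, ELOVL7 (-2.45 ± 0.08), AADAT (-2.28 ± 0.07), HES6 (-2.20 ± 0.10) and SLC45A3 (-1.99 ± 0.06) fell. The largest adjusted p among these genes was 6.13e-11 (HES6), and their 3 and 3 libraries did not overlap. NOS3 (chromosome 7, 150990995 to 151014588, plus strand) was at 0.244 ± 0.0322 RPKM in siNC and 27.4 ± 0.579 after siPDIA5, and HSD11B2 went from 27.0 to 213. A total of 5972 genes were called, 2433 higher and 3539 lower, with 259 up and 209 down by at least 2-fold. Median centring gave 2958 higher and 2941 lower and quantile normalization 2818 and 3174.

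After siPDIA5 at 96 h KLK3 (ENSG00000142515.15, chromosome 19, 50854915 to 50860764, plus strand) rose from 291 ± 17.2 to 602 ± 5.77 RPKM (1.05 ± 0.05, adjusted p = 7.64e-11) and KLK2 (chromosome 19, 50861568 to 50880567, plus strand) from 61.1 ± 5.6 to 91.0 ± 1.78 (0.57 ± 0.07, adjusted p = 2.58e-06). TMPRSS2 (-0.41 ± 0.04, adjusted p = 7.94e-07) and FKBP5 (-0.30 ± 0.07, adjusted p = 0.00192) fell. KLK2 has a close paralog among the measured genes, so its values may include shared reads.

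**Figure D3:**
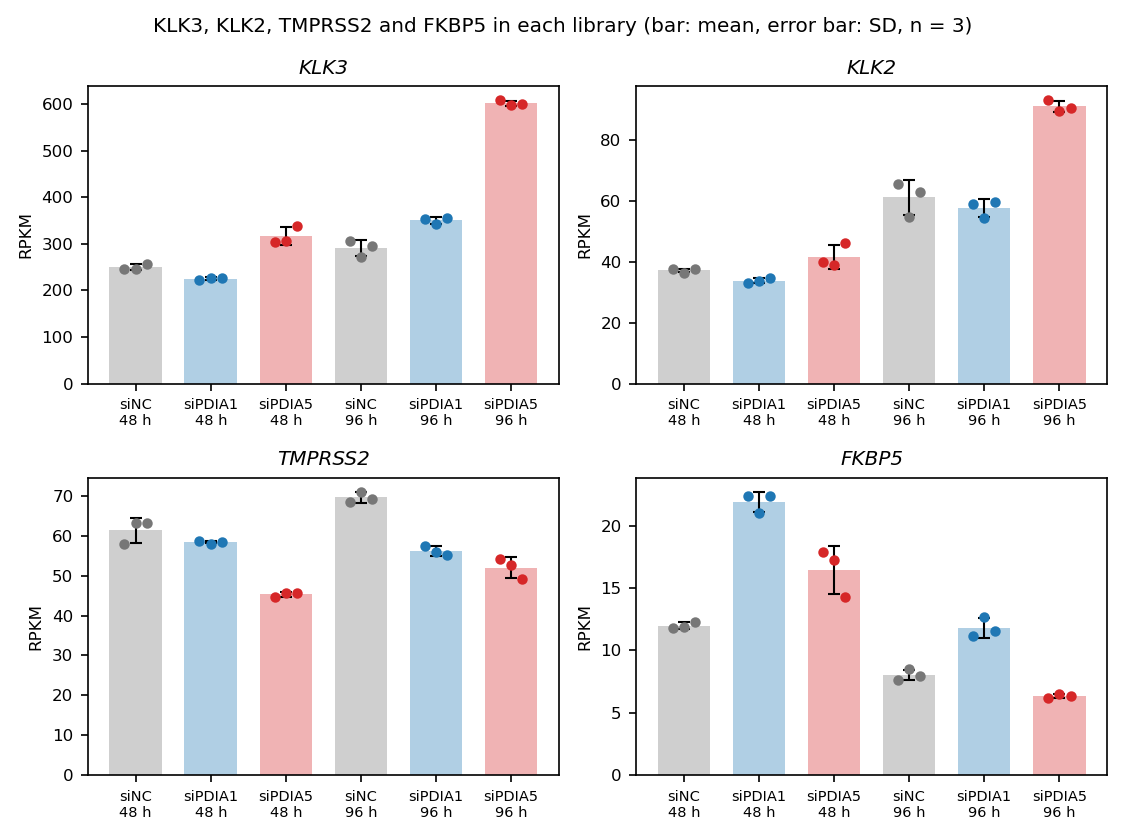
RPKM of KLK3, KLK2, TMPRSS2 and FKBP5 in each of the 18 libraries, by siRNA and time, with bars for the group mean and error bars for the SD (n = 3). At 96 h KLK3 is at 602 RPKM after siPDIA5 against 291 in siNC.

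ATF4 targets rose after siPDIA5 at 96 h, and of 34 genes 29 rose, 0 fell and 5 did not pass (29 and 0 adjusted over the list alone). They included the tRNA synthetase AARS1 (0.92 ± 0.04), PCK2 of mitochondrial gluconeogenesis (1.30 ± 0.06), ATF4 itself (0.98 ± 0.05) and the mTORC1 inhibitor DDIT4 (1.13 ± 0.06). The ATF4 target list had a median of 0.76 (camera adjusted p = 1.7e-15, adjusted p = 0.000349 with an estimated correlation). Of 41 ER chaperone genes 23 rose, 4 fell and 14 did not pass (24 and 4 adjusted over the list alone). Among them HERPUD1 (1.26 ± 0.05), HSPA5 (0.56 ± 0.04) and the ubiquitin ligase SYVN1 (0.53 ± 0.04) were higher and SEC61B lower (-0.76 ± 0.07). The ER chaperone list had a median of 0.21 (camera adjusted p = 3.69e-05, adjusted p = 0.00208 with an estimated correlation). Of 17 PDI family genes 9 rose, 1 fell and 7 did not pass (11 and 1 adjusted over the list alone). Among them PDIA3 (0.40 ± 0.05) and PDIA4 (0.34 ± 0.04) were higher (median 0.18, camera adjusted p = 0.010, adjusted p = 0.0346 with an estimated correlation). Every S phase gene that passed fell, and of 44 genes 0 rose, 41 fell and 3 did not pass (0 and 41 adjusted over the list alone). They included RRM2 (-1.46 ± 0.05), MCM7 (-1.42 ± 0.06) and FEN1 (-1.24 ± 0.05). The S phase list had a median of -0.88 (camera adjusted p = 8.78e-17, adjusted p = 0.00130 with an estimated correlation). Likewise of 55 G2/M genes 0 rose, 52 fell and 3 did not pass (0 and 52 adjusted over the list alone). They included the ubiquitin-conjugating enzyme UBE2C (-1.70 ± 0.08), the anaphase activator CDC20 (-1.66 ± 0.08), PLK1 (-1.55 ± 0.06) and the kinase CDK1 (-1.08 ± 0.06). The G2/M list had a median of -0.96 (camera adjusted p = 3.08e-19, adjusted p = 0.00155 with an estimated correlation). NF-kB targets rose, and of 9 genes 8 rose, 0 fell and 1 did not pass (8 and 0 adjusted over the list alone). Foremost were NFKB1 (0.72 ± 0.07) and the apoptosis inhibitor BIRC3 (1.06 ± 0.12). The NF-kB target list had a median of 0.47 (camera adjusted p = 0.000289, adjusted p = 0.00668 with an estimated correlation). Of 25 apoptosis genes 12 rose, 5 fell and 8 did not pass (12 and 5 adjusted over the list alone). Among them the BAX-like BOK (0.89 ± 0.08) was higher and BMF lower (-0.87 ± 0.07). The apoptosis list had a median of 0.17 (camera adjusted p = 0.0242, adjusted p = 0.0472 with an estimated correlation). The neuroendocrine list had only 2 tested members, SYT4 (2.20 ± 0.05) and the glycolytic enzyme ENO2 (0.73 ± 0.14), and both rose (median 1.46, camera adjusted p = 0.00629, adjusted p = 0.0346 with an estimated correlation). Without the expression filter the list held 17 genes and was not called (median 0, adjusted p = 0.672), and CHGA of this list was at most 0.0721 RPKM in any library.

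Several lists called at 96 h after siPDIA5 were lost with an estimated correlation. Of 26 NRF2 targets 15 rose, 3 fell and 8 did not pass (15 and 3 adjusted over the list alone). Among them HMOX1, EPHX1 (0.98 ± 0.05), the ferritin heavy chain FTH1 (1.88 ± 0.11), which has many pseudogenes, and the quinone reductase NQO1 (1.07 ± 0.07) were higher (median 0.20, camera adjusted p = 0.000304, adjusted p = 0.0503 with an estimated correlation). Of 72 nuclear-encoded oxidative phosphorylation genes 0 rose, 36 fell and 36 did not pass (0 and 36 adjusted over the list alone). Among them the complex I subunit NDUFB10 (-1.03 ± 0.08) and the ATP synthase subunit ATP5F1A (-0.52 ± 0.04) were lower (median -0.24, camera adjusted p = 0.000284, adjusted p = 0.505 with an estimated correlation). Mitochondrial ribosome genes fell, and of 56 genes 0 rose, 32 fell and 24 did not pass (0 and 33 adjusted over the list alone). Foremost was MRPS27 (-1.0 ± 0.04). The mitochondrial ribosome list had a median of -0.28 (camera adjusted p = 0.000180, adjusted p = 0.312 with an estimated correlation). Cytosolic ribosome genes were lower, and of 74 genes 0 rose, 36 fell and 38 did not pass (0 and 36 adjusted over the list alone). Foremost were RPL22 (-0.74 ± 0.07) and RPL4 (-0.42 ± 0.06). The cytosolic ribosome list had a median of -0.23 (camera adjusted p = 0.00107, adjusted p = 0.615 with an estimated correlation), and this call was lost without siNC replicate 1 at 96 h (median -0.14, adjusted p = 0.0586). Of 24 cholesterol synthesis genes 3 rose, 13 fell and 8 did not pass (3 and 14 adjusted over the list alone). Among them ACAT2 (-0.94 ± 0.06) was lower and TM7SF2 (0.81 ± 0.05) higher (median -0.23, camera adjusted p = 0.0285, adjusted p = 0.0503 with an estimated correlation), and the call was also lost at a mean RPKM of at least 5 (0.0906) and with quantile normalization (0.0662). Mitochondrially encoded genes were higher as a list, and of 13 genes 2 rose, 0 fell and 11 did not pass (0 adjusted over the list alone). They included MT-ND4 (0.26 ± 0.08) and MT-CO1 (0.18 ± 0.06). The mitochondrially encoded list had a median of 0.16 (camera adjusted p = 0.0352, adjusted p = 0.510 with an estimated correlation), and their share of reads was 12.6% to 13.9% against 10.1% to 11.1% in siNC. That call was lost with quantile normalization, where the median was 0, and without siNC replicate 1 (adjusted p = 0.0586), siNC replicate 3 (0.0901) or siPDIA5 replicate 3 (0.130) at 96 h, which also ended the MT-CO1 call (0.0838, 0.0891 and 0.141) and, for the last, that of MT-ND4 (0.0571). Neither gene was called without the expression filter (0.295 for MT-ND4 and 0.545 for MT-CO1), with quantile normalization (1.0 and 0.297) or in a fit of only the groups compared (0.108 and 0.239). Of 3 measured markers of basal epithelium, the laminin subunit LAMB3 (0.98 ± 0.10) and the integrin ITGA3 (0.62 ± 0.09) rose and EGFR did not pass (0.08 ± 0.12). The basal list had a median of 0.62 (camera adjusted p = 0.0285, adjusted p = 0.0727 with an estimated correlation), and the call was lost with quantile normalization (0.0514), without the expression filter (15 genes, 0.0556) and at a mean RPKM of at least 5 (1 gene, 0.762).

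Lists that were not called at 96 h after siPDIA5 also held strong single changes. Of 20 heat shock genes 6 rose, 7 fell and 7 did not pass. Among them CRYAB and HSPB1 (1.83 ± 0.08) were higher and HSP90AB1 lower (-0.46 ± 0.04), and the median (-0.03) and mean (0.17) differed in sign (camera adjusted p = 0.618). Of 30 p53 targets 7 rose, 11 fell and 12 did not pass. Among them the stress cytokine GDF15 was higher (1.61 ± 0.06) and the pore-forming protein BAX lower (-0.60 ± 0.06), and the list was not called (camera adjusted p = 0.797). Of 27 hypoxia and glycolysis genes 5 rose, 12 fell and 10 did not pass. Among them VEGFA was higher (1.13 ± 0.05) and lactate dehydrogenase LDHA lower (-0.67 ± 0.07), and the list was not called (camera adjusted p = 0.617). Of 17 interferon genes 8 rose, 4 fell and 5 did not pass. Among them IRF7 was higher (1.11 ± 0.07), and the list was not called (camera adjusted p = 0.163). Of 31 proteasome genes 2 rose, 13 fell and 16 did not pass. Among them PSMA5 was lower (-0.52 ± 0.06), and the list was not called (camera adjusted p = 0.163). Of 18 fatty acid synthesis genes 4 rose, 9 fell and 5 did not pass. Among them ELOVL7 and ELOVL6 (-0.86 ± 0.08) were lower (camera adjusted p = 0.222). Of 15 extracellular matrix genes 4 rose, 5 fell and 6 did not pass. Among them FN1 was higher (1.52 ± 0.09), and the list was not called (camera adjusted p = 0.555). Among cell type markers, smooth muscle actin ACTA2 fell (-1.70 ± 0.08) and COL1A1 did not pass (-0.15 ± 0.09) in the stromal list (camera adjusted p = 0.0951), and VWF, the only endothelial marker tested, rose (0.45 ± 0.09, list adjusted p = 0.163).

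**Figure D4:**
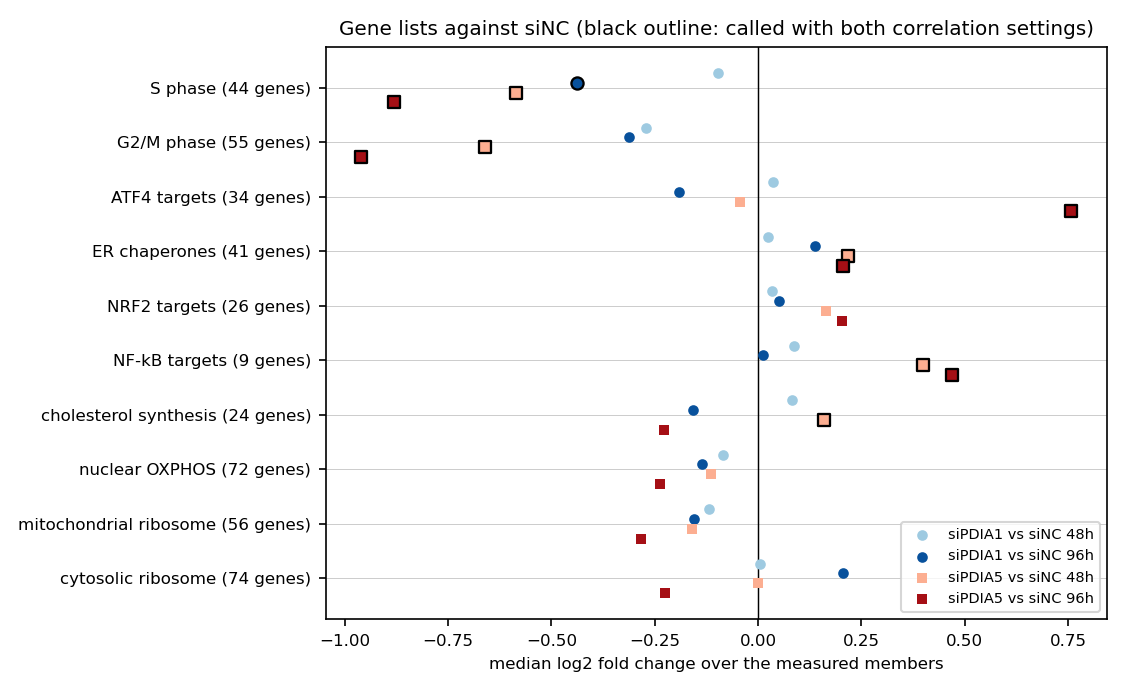
Median log2 fold change against siNC over the measured members of 10 gene lists, for siPDIA1 (circles) and siPDIA5 (squares) at 48 h (light) and 96 h (dark), with a black outline where a list was called with both the preset and an estimated correlation. S phase reaches -0.88 and G2/M -0.96 with siPDIA5 at 96 h, where ATF4 targets stand at 0.76 against -0.19 with siPDIA1.

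The knockdowns were then compared directly. At 48 h PERP, a desmosome-associated p53 target, was higher after siPDIA1 than after siPDIA5 (log2 difference 2.05 ± 0.05, n = 3 per group), and PRRC2A (2.01 ± 0.07) likewise. The RNA-binding protein RBM24 (-2.61 ± 0.10), the secreted protein OAF (-1.93 ± 0.07), PLA2G2A (-1.86 ± 0.13) and JUP, the junctional plakoglobin (-1.83 ± 0.04), were lower (largest adjusted p = 2.16e-08, for PLA2G2A). S phase and G2/M genes were higher after siPDIA1. Of 44 S phase genes, 37 were higher, 2 lower and 5 did not pass (39 and 3 adjusted over the list alone), as in TYMS (1.43 ± 0.07). The S phase median difference was 0.47 (camera adjusted p = 1.47e-08, adjusted p = 0.0129 with an estimated correlation). Of 55 G2/M genes, 39 were higher, 2 lower and 14 did not pass (40 and 3 adjusted over the list alone), as in HMGB2 (0.91 ± 0.07). The G2/M median difference was 0.39 (camera adjusted p = 1.33e-06, adjusted p = 0.0481 with an estimated correlation). Heat shock, ER chaperone and NF-kB target lists were lower after siPDIA1. Of 20 heat shock genes, 1 were higher, 16 lower and 3 did not pass (1 and 17 adjusted over the list alone), as in HSPB1 (-1.24 ± 0.08). The heat shock median difference was -0.29 (camera adjusted p = 5.77e-08, adjusted p = 0.0129 with an estimated correlation). Of 41 ER chaperone genes, 6 were higher, 16 lower and 19 did not pass (6 and 17 adjusted over the list alone), as in HSPA5 (-0.53 ± 0.04). The ER chaperone median difference was -0.15 (camera adjusted p = 0.00102, adjusted p = 0.0129 with an estimated correlation). Of 9 NF-kB targets, 1 were higher, 6 lower and 2 did not pass (1 and 6 adjusted over the list alone), as in NFKB2 (-0.66 ± 0.05). The NF-kB target median difference was -0.29 (camera adjusted p = 0.00130, adjusted p = 0.0162 with an estimated correlation). Among lists that were not called, median, mean and camera direction differed in sign for PDI family (0.06, -0.14, down), oxidative phosphorylation (0.03, 0.05, down), mitochondrial ribosome (0.01, 0.01, down), hypoxia (-0.02, 0.03, down) and interferon (-0.09, 0.01, down). In all 4813 genes differed, 3070 higher and 1743 lower after siPDIA1. Median centring turned this split to 2230 higher and 2423 lower, and quantile normalization gave 2278 and 2248. Lists called only with the preset correlation were NRF2 targets (adjusted p = 0.0171, and 0.230 with an estimated correlation), proteasome (0.0215 and 0.482), fatty acid synthesis (0.0143 and 0.343) and extracellular matrix (0.0295 and 0.0712), each with a median lower after siPDIA1. These were lost at a mean RPKM of at least 5 (adjusted p = 0.0876, 0.0876, 0.0816 and 0.0767 in that order) and with quantile normalization (0.282, 0.306, 0.306 and 0.101), extracellular matrix also without the filter (0.168, median 0.01), and proteasome without siPDIA5 replicate 3 (0.116).

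At 96 h ACTA2 (2.77 ± 0.08), TRPM8 (2.74 ± 0.10) and EFNB2 (2.62 ± 0.14) were higher after siPDIA1 than after siPDIA5, and HSD11B2 (-3.35 ± 0.07), the natriuretic peptide NPPC (-3.01 ± 0.15) and NOS3 (-2.82 ± 0.11) were lower (n = 3 per group, largest adjusted p = 4.78e-10, for EFNB2). ATF4 targets were lower after siPDIA1, and of 34 genes 0 were higher, 31 lower and 3 did not pass (0 and 31 adjusted over the list alone). They included CHAC1, which degrades glutathione (-2.55 ± 0.11), and PCK2 (-1.66 ± 0.06). In ATF4 target genes the median difference was -0.88 (camera adjusted p = 5.64e-20, adjusted p = 8.16e-05 with an estimated correlation). S phase and G2/M genes were higher. Of 44 S phase genes, 33 were higher, 2 lower and 9 did not pass (35 and 2 adjusted over the list alone), as in TYMS (1.28 ± 0.07). In S phase genes the median difference was 0.49 (camera adjusted p = 1.53e-08, adjusted p = 0.0169 with an estimated correlation). Of 55 G2/M genes, 48 were higher, 1 lower and 6 did not pass (48 and 1 adjusted over the list alone), as in PLK1 (0.94 ± 0.06). In G2/M genes the median difference was 0.62 (camera adjusted p = 5.61e-14, adjusted p = 0.00967 with an estimated correlation). NF-kB targets were lower. Of 9 NF-kB targets, 0 were higher, 7 lower and 2 did not pass (0 and 7 adjusted over the list alone), as in NFKB2 (-1.03 ± 0.05). In NF-kB target genes the median difference was -0.60 (camera adjusted p = 0.00151, adjusted p = 0.0174 with an estimated correlation). Cytosolic ribosome and oxidative phosphorylation genes were higher and heat shock genes lower with the preset correlation alone. Of 74 cytosolic ribosome genes, 59 were higher, 1 lower and 14 did not pass (61 and 1 adjusted over the list alone), as in RPS12 (0.82 ± 0.08). In cytosolic ribosome genes the median difference was 0.40 (camera adjusted p = 1.22e-09, adjusted p = 0.559 with an estimated correlation). Of 72 oxidative phosphorylation genes, 29 were higher, 1 lower and 42 did not pass (25 and 1 adjusted over the list alone). In oxidative phosphorylation genes the median difference was 0.13 (camera adjusted p = 0.0333, adjusted p = 0.814 with an estimated correlation). Of 20 heat shock genes, 2 were higher, 9 lower and 9 did not pass (2 and 9 adjusted over the list alone). In heat shock genes the median difference was -0.11 (camera adjusted p = 0.0176, adjusted p = 0.170 with an estimated correlation). Signs of median, mean and camera direction differed for PDI family (0.05, -0.04, down), proteasome (0.00, -0.01, down), p53 (0.05, -0.05, down), cholesterol synthesis (0.08, -0.01, down), basal (-0.23, 0.02, down) and neuroendocrine (-0.08, -0.08, up), all uncalled. At a mean RPKM of at least 5 the NF-kB (adjusted p = 0.0531), heat shock (0.0720) and oxidative phosphorylation (0.0720) calls were lost, the last also with protein-coding genes only (0.0603) and without siPDIA1 replicate 2 (0.136) or siPDIA5 replicate 3 (0.0523). A total of 5672 genes differed, 3234 higher and 2438 lower after siPDIA1, against 2883 and 2708 with median centring.

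Because both knockdowns at a time were compared with the same siNC libraries, part of their likeness is built in. At 48 h their log2 fold changes correlated at 0.494 across genes, against 0.501 on average in 100 simulations of unchanged groups sharing controls, whereas the covariance was 0.0612 against 0.00987. Both rose for 1008 genes and both fell for 1126, against 310 and 592 for independent lists of the same sizes and 0.01 same-way calls in the simulations. At 96 h the correlation was 0.505, the covariance 0.0978 and the counts 1182 and 1758, against 488 and 893. With 3 control libraries the controls could not be split with 2 on each side, so part of the excess may come from the shared controls. Between siPDIA1 at 48 h and siPDIA5 at 96 h, which share no library, the correlation was 0.382 with 2115 same-way calls, and between siPDIA1 at 96 h and siPDIA5 at 48 h it was 0.389 with 2453. CAMK2N1, SLC7A8, OGFR, ELOVL7, SLC45A3 and HES6 changed in the same direction in all 4 comparisons with siNC.

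The siRNA effects at 96 h were tested against those at 48 h. For siPDIA1 639 genes differed, 292 with a higher and 347 with a lower effect at 96 h, including MMP7 (2.49 ± 0.21), the IGF-binding protein IGFBP3 (1.96 ± 0.11) and the calcium-binding protein S100P (-1.64 ± 0.31). For siPDIA5 2139 genes differed, 1077 higher and 1062 lower, including DIO3 (3.55 ± 0.20), NOS3 (3.36 ± 0.16), HMOX1 (2.37 ± 0.16), CHAC1 (2.26 ± 0.16), FKBP5 (-0.72 ± 0.10) and ACTA2 (-1.95 ± 0.11), with n = 3 libraries in each of the 4 groups. Median centring turned these splits to 348 higher and 300 lower for siPDIA1 and 952 and 1178 for siPDIA5. ATF4 targets moved in opposite directions between the times, with a median difference of -0.25 for siPDIA1 (0 were higher, 12 lower and 22 did not pass of 34, 1 and 18 adjusted over the list alone, camera adjusted p = 1.99e-09) and 0.71 for siPDIA5 (27 were higher, 0 lower and 7 did not pass, 31 and 0 adjusted over the list alone, camera adjusted p = 2.9e-23). The largest adjusted p among the named genes was 0.00548 (S100P, siPDIA1).

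The siNC libraries at 96 h were compared with those at 48 h for changes with time after transfection. At 96 h the proliferation marker MKI67 (-0.91 ± 0.13), the ETS factor ETV1 (-0.90 ± 0.09) and ACTRT3, an actin-related protein (-0.86 ± 0.16), were lower (n = 3 per group, adjusted p = 0.000160, 7.97e-06 and 0.00139). The 5 largest rises were all in features under 200 bases, which are uncertain. Of 44 S phase genes 0 rose, 33 fell and 11 did not pass (1 and 36 adjusted over the list alone). They included RRM2 (-0.67 ± 0.05). Over S phase genes the median was -0.37 (camera adjusted p = 6.03e-16, adjusted p = 0.00164 with an estimated correlation), and of 55 G2/M genes 0 rose, 49 fell and 6 did not pass (0 and 52 adjusted over the list alone), including TMPO (-0.66 ± 0.06). Over G2/M genes the median was -0.54 (camera adjusted p = 1.45e-27, adjusted p = 0.000888 with an estimated correlation). KLK2 rose (0.70 ± 0.07, adjusted p = 7.1e-06) and FKBP5 fell (-0.52 ± 0.07, adjusted p = 0.000114). ACTA2 (1.48 ± 0.08) and COL1A1 (0.39 ± 0.09), the 2 stromal markers tested, rose (median 0.94, camera adjusted p = 0.00135, adjusted p = 0.0324 with an estimated correlation). Of 30 p53 targets 10 rose, 1 fell and 19 did not pass (12 and 1 adjusted over the list alone). Among them CDKN1A (0.87 ± 0.04) and GDF15 (1.04 ± 0.06) were higher (median 0.13, camera adjusted p = 0.00135, adjusted p = 0.0649 with an estimated correlation), and of 74 cytosolic ribosome genes 27 rose, 0 fell and 47 did not pass (47 and 0 adjusted over the list alone), with RPL5 higher (0.24 ± 0.05). Over cytosolic ribosome genes the median was 0.21 (camera adjusted p = 1.56e-11, adjusted p = 0.469 with an estimated correlation). Also called only with the preset correlation were oxidative phosphorylation (up, adjusted p = 1.09e-05, and 0.486 with an estimated correlation), mitochondrially encoded genes (up, 0.0118 and 0.486, with shares of reads of 9.50% to 9.88% at 48 h and 10.1% to 11.1% at 96 h), mitochondrial ribosome (up, 0.0459 and 0.641), NF-kB targets (up, 0.00789 and 0.0502), apoptosis (up, 0.0212 and 0.0566), extracellular matrix (up, 0.0144 and 0.0566) and ATF4 targets (down, 0.0147 and 0.0999). At a mean RPKM of at least 5 the calls of NF-kB targets (adjusted p = 0.0510), apoptosis (0.0777), mitochondrial ribosome (0.0984) and extracellular matrix (0.442) were lost, as were the stromal call without the filter (0.0703) and the mitochondrial ribosome (0.0949) and mitochondrially encoded (0.952) calls with quantile normalization. Omission of siNC replicate 2 at 96 h ended the mitochondrially encoded (0.130) and ATF4 (0.0717) calls, and that of replicate 2 (0.121) or 3 (0.0628) at 48 h or 1 (0.501) or 3 (0.110) at 96 h the mitochondrial ribosome call. In all 2839 genes differed, 1285 higher and 1554 lower, but 27 rose and 1 fell by at least 2-fold, and the count was 1085 in a fit of only the groups compared, 1655 without siNC replicate 1 at 96 h, 1845 without replicate 3 at 96 h and 1856 without replicate 2 at 48 h.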

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

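The counts of other splits were planned before the results were seen, whereas the restriction of the list differences given here to lists called with both correlation settings, and the settings tried on these lists and on TMPRSS2, were chosen after. Each result in this part differed between the times in a test of the difference itself, the siRNA effect at 96 h minus that at 48 h (limma adjusted p under 0.05, n = 3 libraries in each of 4 groups).

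For siPDIA1 639 genes differed. The reduction of P4HB was smaller at 96 h (log2 difference 0.55, adjusted p = 0.00272). KLK3 moved from slightly lower to higher (0.41, adjusted p = 0.00178), while TMPRSS2 moved down (-0.23, adjusted p = 0.0334). The TMPRSS2 call was lost without the filter (0.0575), with quantile normalization (0.230), without the trend (0.0661), with only the groups compared (0.0559) and on leaving out siNC replicate 1 at 48 h or 3 at 96 h, any siPDIA1 replicate at 48 h, or siPDIA1 replicate 2 or 3 at 96 h (0.0660 to 0.0848). MMP7 (2.49) and IGFBP3 (1.96) had higher effects at 96 h. S100P had a lower effect (-1.64). Other large differences were in short, non-coding or unnamed features whose reads are uncertain, namely MIR3189 (3.11), ENSG10010138831.1 (2.34), RP11-693J15.6 (2.10), SNORA9B (-2.40), MIR1244-2 (-1.71) and CTD-2523D13.2 (-1.43). Without the filter the calls of MIR3189 (adjusted p = 0.118), SNORA9B (0.166), MIR1244-2 (0.130) and CTD-2523D13.2 (0.0521) were lost. MIR3189 was also lost with a pseudocount of 0.25 (0.0774), SNORA9B without the trend (0.0560), and SNORA9B (0.0694) and MIR1244-2 (0.0766) with only the groups compared. Each of these 3 was lost without the 2 farthest libraries (0.0666, 0.0988 and 0.0576 for MIR3189, SNORA9B and MIR1244-2) and on leaving out 8 of the 12 libraries in turn (0.0552 to 0.125). Among the lists, the median difference was -0.25 for ATF4 targets, 0.12 for ER chaperones, -0.25 for S phase, -0.32 for cholesterol synthesis and 0.96 for the 2 neuroendocrine genes tested, a call lost without the filter (adjusted p = 0.279).

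For siPDIA5 2139 genes differed. KLK3 (0.71, adjusted p = 4.83e-06) and KLK2 (0.41, adjusted p = 0.00613) moved up and FKBP5 (-0.72, adjusted p = 0.000143) down. DIO3, which inactivates thyroid hormone (3.55), NOS3 (3.36), HMOX1 of haem breakdown (2.37) and CHAC1 (2.26) had higher effects at 96 h. Smooth muscle actin ACTA2 (-1.95), the thyroid hormone carrier TTR (-1.51) and THRSP (-1.38) had lower effects. MIR3189 (2.57), ENSG10010136505.1 (-1.87) and ENSG00000279413 (-1.61) are uncertain features. The call of MIR3189 was lost with a pseudocount of 0.25 (adjusted p = 0.0596), without the filter (0.131), with only the groups compared (0.0517) and on leaving out 7 of the 12 libraries in turn (0.0701 to 0.0853). That of ENSG10010136505.1 was lost without the filter (0.137), with only the groups compared (0.0527), without the 2 farthest libraries (0.0782) and on leaving out 9 of the 12 in turn (0.0524 to 0.0966). The list medians were 0.71 for ATF4 targets, -0.20 for S phase, -0.31 for G2/M, -0.44 for cholesterol synthesis, -0.32 for fatty acid synthesis and 0.92 for the 2 neuroendocrine genes, also lost without the filter (0.899).

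In 100 drawn splits of the libraries, 8 gave as many genes as the real 639 for siPDIA1, the real split included, with 3275 the highest of the others, and 8 gave as many as the real 2139 for siPDIA5, with 4118 the highest, so chance was not excluded by this count. In each case the 7 others exchanged siRNA labels mainly at 1 time, which turns the effect itself into a difference and points to a structure of the samples. For the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real split, 1 of 10 in each, called 3897 genes for siPDIA1 at 48 h, 5294 for siPDIA1 at 96 h, 5972 for siPDIA5 at 96 h, 4813 and 5672 between the knockdowns and 2839 for time in siNC, where the highest other split called 0, and 5352 for siPDIA5 at 48 h, where the highest other called 1.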

How the results depend on the processing

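The tests with protein-coding genes only, without the 2 libraries farthest from their group mean, of the lists under settings other than the estimated correlation, and of genes fixed by name in comparisons other than those with siNC were chosen after the data were seen. Across the settings other than leaving out a replicate, 4525 values of named genes kept direction and side of the threshold, 95 lost their call and 22 gained one. Among lists, 2130 kept it, 111 lost a call, 51 gained one and 3 reversed. Most of the gains came without the filter, where, against siNC, proteasome, oxidative phosphorylation and hypoxia were called for siPDIA1 at 48 h, and PDI family, NRF2 targets, heat shock, proteasome, oxidative phosphorylation, fatty acid synthesis, extracellular matrix, stromal and basal lists at 96 h. For siPDIA5 these were oxidative phosphorylation, mitochondrial ribosome and interferon at 48 h, and proteasome, fatty acid synthesis, hypoxia and interferon at 96 h. At a mean RPKM of at least 5, which left 6493 genes to test, 3505 were called for siPDIA5 at 48 h (5352 in the full set), and 3058 and 3775 between the knockdowns (4813 and 5672). A fit of only the groups compared called 1085 genes for time in siNC (2839), with fewer libraries behind the spread. The mitochondrially encoded list at 96 h after siPDIA5 had a median of 0 with quantile normalization (adjusted p = 0.882), as had that for time in siNC (0.952), and the cause was not tested. At a mean RPKM of at least 5, which left 1 basal gene, the basal effect difference for siPDIA1 went from 0.22 to -0.14 (0.761). Leaving out each replicate in turn gave 3196 to 3410 genes for siPDIA1 at 48 h, 4626 to 5190 at 96 h, 4750 to 4955 for siPDIA5 at 48 h, 5322 to 5859 at 96 h, 4086 to 4390 and 4962 to 5145 between the knockdowns, 434 to 825 and 1694 to 2703 for the effect differences, and 1655 to 3882 for time in siNC, where omission of siNC replicate 1 (1655) or 3 (1845) at 96 h or replicate 2 at 48 h (1856) moved the count by over 1.5 times. Leaving out 1 library gave 28 list calls that the full set lacked, lost 30 and reversed 1, the oxidative phosphorylation effect difference for siPDIA1 without siNC replicate 2 at 96 h (adjusted p = 0.0235, medians of -0.112 to 0.0504 over the omissions, the cause was not tested). Those gained against siNC were oxidative phosphorylation for siPDIA1 without siNC replicate 2 at 48 h (adjusted p = 0.0472) and at 96 h (0.00538) and for siPDIA5 at 48 h without its replicate 3 (0.0320), proteasome at 96 h for siPDIA1 without siNC replicate 2 (0.00538) or siPDIA1 replicate 2 (0.0459) and for siPDIA5 without siNC replicate 2 (0.0298), and at 48 h for siPDIA5 mitochondrial ribosome without siPDIA5 replicate 3 (0.0196) and cytosolic ribosome without siPDIA5 replicate 1 (0.0158). A block for the replicate number called 3772, 5215, 5278 and 5898 genes against siNC, 4757 and 5585 between the knockdowns, 590 and 2008 for the effect differences and 2722 for time in siNC, and ended the heat shock call for siPDIA1 at 48 h (0.0545), the cholesterol call at 96 h (0.0531) and the TMPRSS2 effect difference for siPDIA1 (0.0512). Deviations of same-numbered libraries correlated at a median of 0.008 (-0.257 to 0.139, 4 of 45 pairs over 0.1). Within an siRNA these lay at -0.036 to 0.139. Not every library correlated best with its own number, but weak pairing stays open. Median centring moved the split for siPDIA5 at 48 h from 1944 higher and 3408 lower to 2574 and 2420. Without the 2 farthest libraries 4882 genes were called for siPDIA1 at 96 h and 4958 for siPDIA5 at 48 h. No setting varied depth, and replicate pairs gave a chi-square of 7.23 to 48.7 per degree of freedom against counting noise, so for the genes compared the spread between libraries exceeded that from counting.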

Other observations

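The word scan of 3′ UTRs, the words tested at 96 h, the siNC word, the noise of the shared controls and the tests of the cell cycle lists were chosen after the results were seen. The tests of words in the target transcripts and of pairs 10 bases apart were written before their results. The 5% bar that leaves the word tests undecided and the reading of the pair tests as undecided were set after.

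Genes lower after each siRNA shared short words in their 3′ UTRs (ACAGAGT with siPDIA1, z = -9.52 at 48 h over 1853 genes, and GAGAGAA with siPDIA5, z = -12.4 over 2172 genes), the hypothesis being off-target binding through the seed of an siRNA strand. Sampling noise of the 48 h libraries is argued against by z = -6.45 and -7.46 at 96 h. P4HB holds 0 pairs of selected words within 30 bases. P4HB holds 2 of 2 selected words and PDIA5 2 of 3, but 34.6% and 33.5% of genes of like transcript length hold as many, which leaves a seed match undecided. PDIA5 holds 0 pairs at the 10 bases predicted for a 19-base siPDIA5 duplex and 1 pair 11 bases apart (GGATGATGCCGCATTTCCA, chromosome 3, 123116249 to 123116267, plus strand, coding part of exon 8). Both searches allowed 1 of the forms a seed site can take. The 11 bases were seen before that distance was considered. Thus a 19-base duplex of either siRNA is neither argued against nor supported.

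Genes such as CAMK2N1, SLC7A8 and OGFR were higher in both knockdowns than in siNC, which an effect of the siNC duplex itself might give. The word CGGAGAA was picked because its genes were higher in both knockdowns at 48 h, but at 96 h its 372 genes also ranked higher than others (z = 6.81 for siPDIA1 and 6.02 for siPDIA5, against the same siNC libraries), which argues against sampling noise of the 48 h libraries for the word. It was carried by 5.08% of the 59 searched genes up at least 2-fold in both at 96 h, against 3.74% of other genes (Fisher's exact test, two-sided, p = 0.486), which leaves open whether it accounts for these genes. Noise of the shared 48 h controls is argued against by the 96 h libraries, where the genes up 2-fold in both at 48 h had medians of 1.48 and 1.26 (SD 0.888 for the latter). A seed effect of siNC and a response common to loss of either enzyme both stay open.

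The S phase and G2/M lists fell after siPDIA5 at 96 h, and 3 technical explanations were set against an effect of PDIA5 loss. Members lacking the 8 words that passed the threshold downward with siPDIA5 at 48 h were taken alone. Their medians were -0.931 (S phase, 16 genes, SD 0.348) and -0.980 (G2/M, 24 genes, SD 0.428). This argues against direct seed binding through these words as the whole cause. Members with the siNC word were not set apart, so a seed effect of siNC was not tested here. Under median centring and quantile normalization the weakest list median was -0.814, and the median of all tested genes was -0.0578, which argues against scaling and against a few abundant transcripts. Indirect effects of off-target binding may still contribute, and a biological effect of PDIA5 loss stays open as a hypothesis.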
